A study of Mus musculus with 10 samples.

How the data were processed

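RNA-seq libraries were made from total RNA of mouse proximal jejunum, 5 labelled WT and 5 labelled cKO, with 1 library per mouse. Per the submitters' processing notes, base calling used CASAVA, reads were aligned with HISAT2 2.0.5 to mm10, counted per gene with featureCounts 1.5.0-p3 and analysed with DESeq2 1.20.0. The strand setting of the counting, the annotation release and the treatment of reads with several matches are not given in the sources used here, so overlapping genes, antisense partners and near-identical copies cannot be told apart with certainty.

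The deposited table gives a normalised signal per gene and library, which are read counts divided by 1 size factor per library, as found from the values. Each value divided by the smallest step of its library was whole within 0.001 for 100% of values in every library, with a largest deviation of 6e-05, and the whole reads were recovered in this way. Recovered reads per library were 17809271, 17048170, 17356616, 17271957 and 16942919 for WT 1, 3, 4, 5 and 6, and 16063987, 17159628, 16927419, 17250173 and 18927440 for cKO 1, 2, 3, 4 and 5. Normalised totals ran from 13417113 in cKO 3 to 20427114 in cKO 1, and mitochondrial genes took 2.69% (WT 5) to 9.48% (cKO 1). The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene. These served only for comparison. An adjusted p of exactly 1 stands beside 9001 genes in the authors' deposited table. The table has 2 further columns of per-sample values whose names match no label, and these were not used.

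The test planned before the data were examined was edgeR on counts, or limma on log values if the table held normalised values. As the unit was normalised values and not counts, limma was the main test. Values were transformed as log2(value + 1), genes with a mean of 10 or more over the 10 libraries were kept (14062 of 24368), and a linear model with genotype alone was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation using an intensity trend and robust hyperparameters. P-values were adjusted by Benjamini-Hochberg over all genes tested. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The edgeR 4.0.16 quasi-likelihood test with TMM factors on recovered reads was added as an alternative and called 163 of 14057 genes. Elavl1 was also tested with an exact two-sided permutation test of the 10 library values. Intervals are at 95%.

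A total of 39 gene lists were fixed before the data were examined: pathways of lipid uptake, synthesis, oxidation, transport and secretion, sterols, digestion, drug metabolism, stress, immunity, the clock and RNA binding, markers of epithelial, stromal, immune, muscle, neural, fat, pancreatic and blood cells and of the duodenal and ileal ends, and quality lists of immediate early, mitochondrial and Y chromosome genes. The 36 lists with at least 5 measured members were tested with camera (preset correlation 0.01), adjusted over the lists, beside camera with an estimated correlation and fry. Named genes followed a rule fixed at the same time: Elavl1; all triglyceride synthesis genes; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a symbol, a mean of at least 100 and no overlap between groups; and from each other list up to 4 genes past the threshold, or no more than 2 with the smallest p given as values. Some genes that the rule picked are not reported here. Other genes were named after their values were seen, and the text says so there.

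The steps were tested on simulated counts drawn from the real means, depths and dispersions of the 10 libraries, with 200 genes changed in each of 5 simulations of the 5 against 5 comparison. Over about 14075 genes limma recovered 8.84% of 1.5-fold changes, 54.8% of 2-fold, 96% of 4-fold and 100% of 8-fold changes, and 5.09% of its calls were false. edgeR over about 14020 genes recovered 6.83%, 54.4%, 96.8% and 100%, with 5.4% false. A shift of 1 list, planted in genes drawn independently, was recovered by camera in 5 of 5 simulations. No 2 libraries of a group were near copies, as the chi-square of their reads over its degrees of freedom was at least 21.5. Correlations within groups were 0.965 to 0.977 in WT and 0.946 to 0.972 in cKO on the log2 scale across genes, which are not independent replicates.

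The alternatives planned were DESeq2 1.42.0, 2 other scalings in edgeR, voom with quality weights, other filters and pseudocounts, library sizes without mitochondrial and top genes, a block for the replicate number, other thresholds and leaving out each library in turn. Added after the data were seen were edgeR with TMM factors, leaving out cKO 3 and cKO 5, a clock covariate, and the 8 libraries with shared numbers without the block. Litters are not mapped to libraries in the labels, so no litter term was fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.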

Results

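Gene expression was measured by RNA-seq in the proximal jejunum, the upper part of the fat-absorbing small intestine, of mice labelled as lacking the RNA-binding protein HuR in the intestinal epithelium and of littermates labelled wild type. HuR is the product of Elavl1 and binds AU-rich and U-rich stretches of messenger RNAs. There were 10 libraries, 5 labelled WT and 5 labelled cKO, each from a separate mouse. The table held 24368 genes as read counts divided by a size factor for each library, and the reads recovered from these values came to between 16063987 (cKO 1) and 18927440 (cKO 5) per library. The comparison asks which transcripts of the jejunum differ when epithelial HuR is deleted, with fat absorption and triglyceride synthesis as the subject named by the study.

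Elavl1 itself, at position 4285382 to 4325413 of chromosome 8 in mm10 (ENSMUSG00000040028), did not differ between the groups past the test (limma adjusted p = 0.798). It stood at 666 ± 36.0 normalised reads in WT (SD, n = 5) and 633 ± 60.6 in cKO (SD, n = 5), with a highest single value of 725 in cKO 1. The log2 fold change was -0.08 with a 95% interval of -0.36 to 0.21, which leaves room for a fall of at most 22.3% (two-sided exact permutation p = 0.325, where the smallest possible is 0.00794). The sign was positive, at 0.033, when the recovered reads were scaled by library totals in edgeR. The deleted exons are not given in the sources used here, so a count over the whole gene does not check the deletion, and every direction given here follows the labels.

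Acta1, the alpha-actin of skeletal muscle (chromosome 8, 123891769 to 123894751), showed the largest rise in the libraries labelled cKO. It went from 271 ± 160 normalised reads in WT to 21359 ± 3135 in cKO (SD, n = 5 each), an 88.1-fold difference on the log2(value + 1) scale (log2 fold change 6.46 ± 0.30 SE, limma adjusted p = 5.27e-08). Its highest WT value was 539 and its lowest cKO value 16174. Reads of actin genes can be shared between near-identical copies, so the level of Acta1 carries that uncertainty. Dock11, an exchange factor for the GTPase Cdc42, rose 3.87-fold (limma adjusted p = 8.41e-05). Ocm, which encodes the calcium-binding protein oncomodulin, rose 3.42-fold (limma adjusted p = 0.000433). Lyve1, a hyaluronan receptor of lymphatic endothelium, rose 3.10-fold, and Tmigd1, an epithelial adhesion protein, rose 3.09-fold. The phosphate cotransporter gene Slc34a2 rose 5.08-fold with a wide spread in cKO, at 5893 ± 5171 (SD, n = 5) against 938 ± 328 in WT (SD, n = 5). The metallothionein gene Mt1 rose 4.51-fold, the lens filament gene Bfsp1 4.18-fold, the retinol-binding protein gene Rbp7 3.98-fold and the kinase gene Mast4 2.77-fold.

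**Figure D1:**
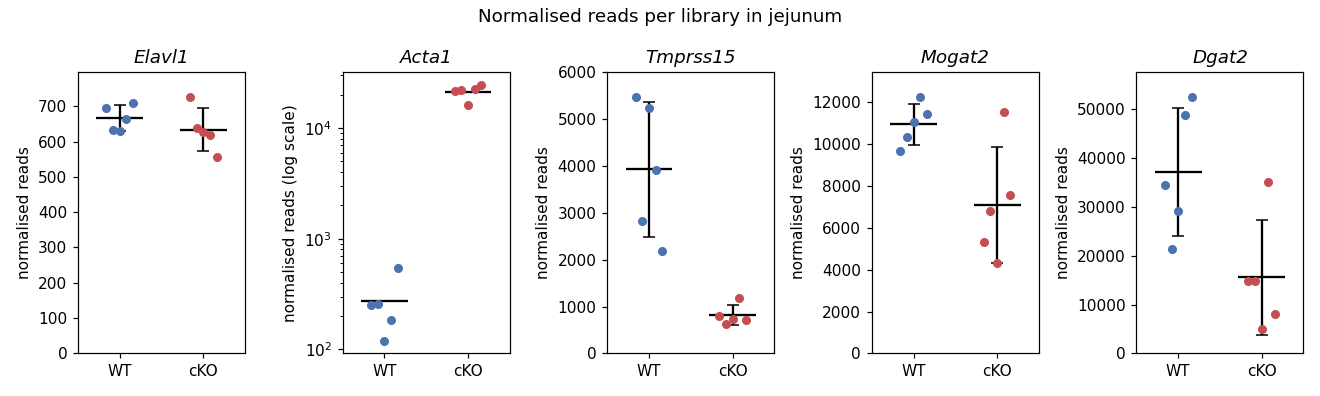
Normalised reads per library (y axis, log scale for Acta1 only) in WT and cKO for Elavl1, Acta1, Tmprss15, Mogat2 and Dgat2. Points are libraries (5 per group), horizontal bars are means and whiskers are SD (not drawn for Acta1). Acta1 lies between 120 and 539 in WT and between 16174 and 24681 in cKO, and Elavl1 overlaps between the groups.

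Most of the genes reported here with the largest falls encode enzymes and carriers. Whether such genes exceed their share among all genes tested was not tested. Tmprss15 (chromosome 16, 78953008 to 79091097) encodes enteropeptidase, the brush border protease that activates trypsinogen, and fell from 3922 ± 1441 to 815 ± 217 normalised reads (SD, n = 5 each), a 4.64-fold fall (log2 fold change -2.21 ± 0.25 SE, limma adjusted p = 0.000433). Cndp1, a dipeptidase for carnosine, fell 4.83-fold (limma adjusted p = 0.000208). Slc46a1, the proton-coupled folate transporter, fell 8.40-fold from 5106 ± 1012 to 751 ± 474 (SD, n = 5 each). The sulfotransferase gene Sult6b2 fell 9.83-fold, but the authors' deposited values give it a log2 fold change of -1.65 (authors' adjusted p = 0.190). The proline transporter gene Slc6a20a fell 6.32-fold, the sulfate transporter gene Slc13a1 4.10-fold and the sterol hydroxylase gene Cyp27a1 4.75-fold. Adh1, an alcohol dehydrogenase gene, fell 3.72-fold, and Tsku, which encodes a secreted leucine-rich repeat protein, 3.64-fold. Of 25 alternatives that refitted the genes, the call was lost in 13 for Adh1, 11 for Sult6b2, 10 for Slc6a20a and Slc34a2, 9 for Cyp27a1 and Mast4, 7 for Rbp7, 5 for Slc13a1 and Tsku, 4 for Slc46a1, 2 for Bfsp1 and 1 for Mt1. These genes and those with the largest rises were taken from genes with no overlap between the 5 WT and 5 cKO values.

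In all, 186 of 14062 genes tested passed a limma adjusted p of 0.05, 62 higher and 124 lower in the libraries labelled cKO. The groups did not overlap for 170 of them; over all genes tested 4.87% showed no overlap, where chance gives 0.794%. The quasi-likelihood test of edgeR on the recovered reads passed 65 higher and 98 lower, and 151 of these 163 genes were also among the 186, with the same sign. In edgeR with library totals the split was 83 higher and 73 lower. In limma with totals that leave out mitochondrial and the most abundant genes it was 73 higher and 87 lower. The median log2 fold change of all genes tested was 0.14 and 0.11 in these fits and 0.010 with the size factors in limma. The count depended strongly on some single libraries. It was 91, 44, 30, 67 and 60 without WT 1, 3, 4, 5 and 6, and 190, 220, 65, 611 and 111 without cKO 1, 2, 3, 4 and 5. In the authors' deposited table, 607 genes had an adjusted p under 0.05, and 168 of the 186 genes were among them, with the same sign for all 168; the libraries behind these p-values were not checked here.

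**Figure D2:**
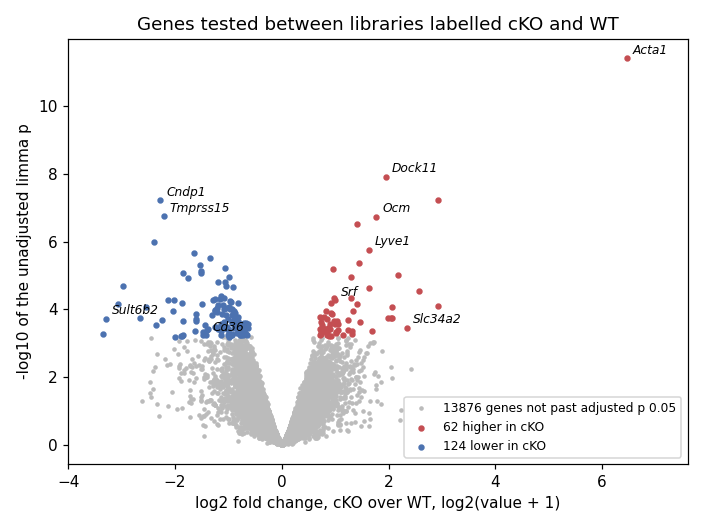
Fold change (x axis, log2 of cKO over WT) against the -log10 of the unadjusted limma p (y axis) for the 14062 genes tested, with the 62 genes higher in cKO in red and the 124 lower in blue. Acta1 stands apart at a log2 fold change of 6.46.

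None of the 15 measured genes of triglyceride synthesis passed the test over all genes, and 12 of them had lower fitted levels in the libraries labelled cKO. Mogat2, which makes diacylglycerol from absorbed monoacylglycerol, stood at 10945 ± 985 in WT and 7095 ± 2779.5 in cKO (SD, n = 5 each; log2 fold change -0.70, limma adjusted p = 0.124). Dgat2 and Dgat1, the acyltransferases of the last step, had log2 fold changes of -1.49 (limma adjusted p = 0.117) and -0.46 (limma adjusted p = 0.227). Dgat2 values were 37185 ± 13083 in WT and 15566 ± 11747 in cKO (SD, n = 5 each), and the cKO 4 value, 35082, lay within the WT range. Among genes of earlier steps, the log2 fold change was -1.13 for the acyl-CoA synthetase gene Acsl3, -0.79 for Acsl1 and -0.24 for Acsl5; it was -0.79, -0.61 and -0.59 for the lysophosphatidate acyltransferase genes Agpat1, Agpat2 and Agpat3. The glycerol phosphate acyltransferase genes gave 0.76 (Gpam), -0.39 (Gpat3) and -0.19 (Gpat4), and the phosphatidate phosphatase genes 0.33 (Lpin1), 0.22 (Lpin2) and -0.22 (Lpin3); Lpin3 turned to 0.065 without cKO 3 and cKO 5. Adjusted over the list alone, 7 genes fell (Acsl3, Agpat1, Agpat2, Agpat3, Mogat2, Dgat2 and Acsl1) and 1 rose (Gpam), against 0 over all genes tested.

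The median log2 fold change of the triglyceride synthesis list was -0.46, and camera with its preset correlation placed the list below other genes (adjusted p = 0.00365). The call was lost at an adjusted p = 0.661 with an estimated correlation. The libraries cKO 3 and cKO 5 differed from the other 8 in clock genes, with Per2 at 12.7 and 16.03 normalised reads against 342 to 749. Without them the list median was -0.24 (camera adjusted p = 0.0423, adjusted p = 0.655 with an estimated correlation). With 1 library left out at a time the list median ran from -0.32 without cKO 3 (camera adjusted p = 0.0123) to -0.61 without cKO 4 (camera adjusted p = 6.78e-05). An estimated correlation was not run in these fits.

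**Figure D3:**
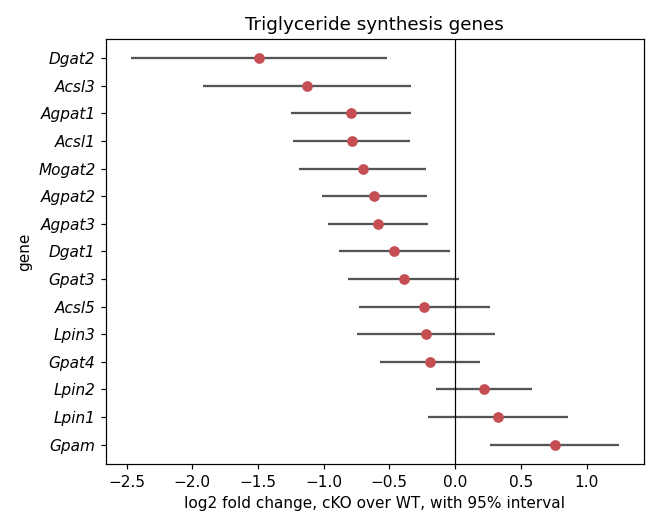
Log2 fold change of cKO over WT (x axis) with its 95% interval from limma for the 15 genes of triglyceride synthesis (y axis). The intervals are for each gene alone, without adjustment; Dgat2 has the lowest value (-1.49) and Gpam the highest (0.76).

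Among the other lipid lists, fatty acid uptake held 2 genes that fell out of 10 measured. These were Cd36, the fatty acid translocase, which fell 2.66-fold (limma adjusted p = 0.0466), and Slc27a2, an acyl-CoA synthetase and fatty acid transport protein, which fell 2.17-fold (limma adjusted p = 0.0272); adjusted over the list alone the same 2 fell. Srebf1, a transcription factor of lipid synthesis, fell 2.28-fold (limma adjusted p = 0.0215) and was the 1 gene of 14 to pass among fatty acid synthesis and desaturation genes, also adjusted over the list alone. None of 14 chylomicron genes passed over all genes and 2 fell adjusted over the list alone, namely Apoa4, an apolipoprotein of chylomicrons (log2 fold change -0.86), and Apoc3 (-0.63). None of the 23 genes of fatty acid oxidation passed in either way; Acaa2 and Hadh had log2 fold changes of -1.01 and -0.52. The chylomicron list had a median of -0.34 (camera adjusted p = 0.00365) and the oxidation list one of -0.30 (camera adjusted p = 0.00552). These calls were lost at adjusted p = 0.661 and adjusted p = 0.683 with an estimated correlation, and without cKO 3 and cKO 5, where the medians were -0.17 and -0.046 (camera adjusted p = 0.0969 and adjusted p = 0.326). Uptake, fatty acid synthesis, cholesterol synthesis and sterol transport had medians of -0.16, 0.16, -0.03 and -0.22 with camera adjusted p of 0.156, 0.599, 0.752 and 0.156; no gene of cholesterol synthesis (25 measured) or sterol transport (9 measured) passed, adjusted over the list alone or over all genes. The cholesterol synthesis median turned positive, to 0.10, with library totals in edgeR.

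Of 22 brush border genes, 21 had lower fitted levels in the libraries labelled cKO and 1, Tmprss15, fell (6 adjusted over the list alone); the median was -0.55 (camera adjusted p = 1.23e-05, adjusted p = 0.661 with an estimated correlation). The villus tip list had a median of -0.44 with 0 of 8 genes past the test and 4 that fell adjusted over the list alone (camera adjusted p = 0.00623, adjusted p = 0.661 with an estimated correlation). Proliferation genes had a median of 0.49 with 17 of 19 positive and none past the test, adjusted over the list alone or over all genes; Ube2c and Ccna2, both cell cycle genes, gave 0.76 and 0.91 (camera adjusted p = 0.00126, adjusted p = 0.661 with an estimated correlation). Crypt base stem cell genes had a median of 0.38, with no gene past the test in either way (camera adjusted p = 0.0334, adjusted p = 0.661 with an estimated correlation), and fry gave this list an adjusted p of 0.0234. Without cKO 3 and cKO 5 the medians were -0.26 for the brush border (camera adjusted p = 0.0136), -0.35 for the villus tip (0.0167) and 0.30 for proliferation (0.0383). These calls were lost there with an estimated correlation (camera adjusted p = 0.655 for each). The stem cell call was lost without cKO 3 and cKO 5 even with the preset correlation, at a median of 0.22 (0.0969). Tuft cell genes had a median of -0.52 with 0 of 8 past the test and 2 that fell adjusted over the list alone (camera adjusted p = 0.0475, adjusted p = 0.683 with an estimated correlation, and adjusted p = 0.0587 without cKO 3 and cKO 5). With 1 library left out, the tuft call was lost without WT 1, WT 3, WT 4, cKO 1, cKO 4 or cKO 5. The camera adjusted p was highest without WT 3 (0.136, median -0.34). The call held without WT 5, WT 6, cKO 2 or cKO 3. Among 16 enteroendocrine genes, Chga (chromogranin A) rose 1.74-fold and Nts (neurotensin) 2.07-fold, both also adjusted over the list alone, while the list median was 0.11 (camera adjusted p = 0.611). Paneth and goblet cell genes had medians of 0.70 (camera adjusted p = 0.281) and -0.15 (camera adjusted p = 0.599), with none past the test in either way. The Paneth median was 1.201 without WT 4 (camera adjusted p = 0.00902), 1.07 without cKO 3 (0.0397) and 0.30 without WT 6 (0.934).

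**Figure D4:**
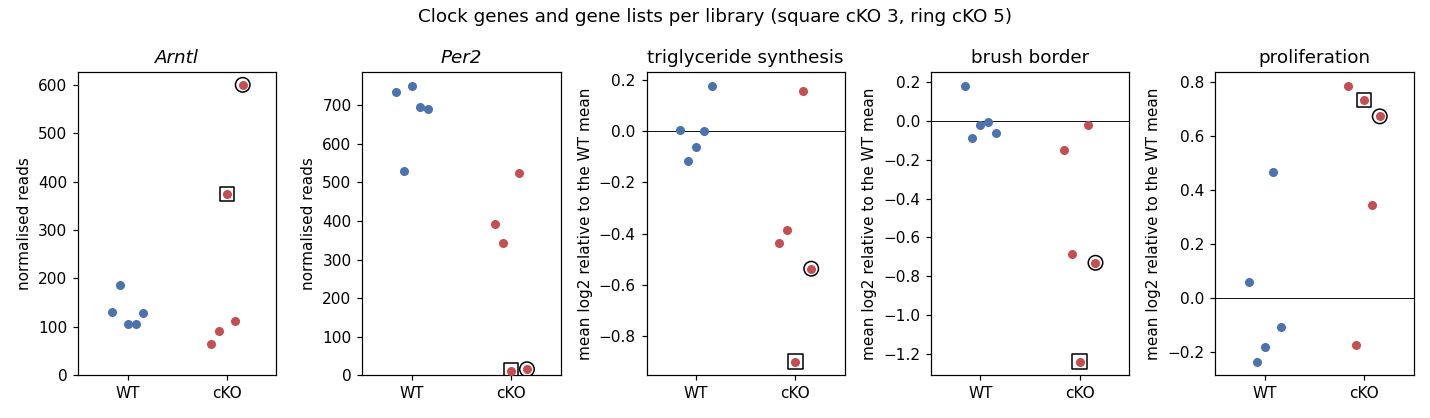
Arntl and Per2 (y axis, normalised reads) and the mean of 3 gene lists (y axis, log2 relative to the WT mean) in each library, with cKO 3 marked by a square and cKO 5 by a ring. Per2 is 12.7 and 16.03 in these 2 libraries, and the triglyceride synthesis and brush border means are lowest there.

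Of 11 fibroblast genes, the collagen genes Col1a1 and Col3a1 rose 2.03-fold and 1.69-fold, and 3 rose and 1 fell adjusted over the list alone; the median was 0.38 (camera adjusted p = 0.00621, adjusted p = 0.661 with an estimated correlation). Of 10 endothelial genes, Lyve1 rose, also adjusted over the list alone. The endothelial median was 0.62 (camera adjusted p = 0.00621, adjusted p = 0.661 with an estimated correlation). Without cKO 3 and cKO 5 it was 0.093 (camera adjusted p = 0.266). The fibroblast median was 0.42 there (camera adjusted p = 0.0136, adjusted p = 0.655 with an estimated correlation). Smooth muscle genes had a median of 0.11 (camera adjusted p = 0.348) and of 0.32 without cKO 3 and cKO 5 (camera adjusted p = 0.0318, adjusted p = 0.655 with an estimated correlation). This change came with cKO 5, as the median was 0.34 without cKO 5 alone (camera adjusted p = 0.0105) and 0.035 without cKO 3 alone (0.692). The medians were -0.36 for neurons and glia (0.230), 0.11 for adipocytes (0.965), 0.01 for T cells (0.970), -0.29 for B and plasma cells (0.212) and 0.10 for myeloid and mast cells (0.965). No gene of these 6 lists passed over all genes, and adjusted over the list alone 1 myeloid gene fell. With 1 library left out at a time, the B and plasma cell median ran from -0.52 (without WT 4) to -0.062 (without WT 5). The neuron and glia median ran from -0.49 (without WT 3) to -0.15 (without WT 5). The 4 erythroid and 2 pancreatic genes measured were too few for camera and had medians of 0.94 and -0.44, with none past the test.

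Of 24 measured messenger RNAs described as HuR targets, Ccnd1, a cyclin gene of cell cycle entry, rose 2.52-fold (limma adjusted p = 0.0254); adjusted over the list alone 4 rose and 4 fell, and the median was 0.13 (camera adjusted p = 0.183). In the xenobiotic list, Cyp2b10, a cytochrome P450 gene, fell 3.04-fold (limma adjusted p = 0.0314), with 2 that rose and 2 that fell adjusted over the list alone. The median was -0.43 (camera adjusted p = 0.148), and it passed without WT 5 (-0.58, 0.00473) and without cKO 1 (-0.52, 0.00984). In the ileal list, Slc51b, a subunit of the basolateral bile acid transporter, rose 1.73-fold, also adjusted over the list alone, while 4 of 5 members were negative (median -0.18, mean -0.20, camera direction up, adjusted p = 0.970). The clock list had a median of -0.92 with none of 16 past the test in either way (camera adjusted p = 0.0194, adjusted p = 0.661 with an estimated correlation), and -0.16 without cKO 3 and cKO 5 (camera adjusted p = 0.109). Its call was also lost without WT 1 alone (camera adjusted p = 0.0583) and without cKO 5 alone (0.0803). No gene passed over all genes in the lists of AU-rich element binding proteins (median -0.03, camera adjusted p = 0.903), p53 targets (-0.06, 0.913), unfolded protein response (0.11, 0.665), interferon response (-0.20, 0.174), MHC class II (-0.16, 0.242), antimicrobial genes (-0.37, 0.246), immediate early genes (-0.20, 0.599), mitochondrial genes (0.20, 0.412) and duodenal genes (0.02, 0.970). Adjusted over the list alone, 1 p53 target rose and 1 fell, 1 gene rose in each of the unfolded protein and immediate early lists, 1 interferon gene fell, and none passed in the other 5. The mean and the test of the AU-rich list were above 0 and its median below, and with library totals in edgeR the medians of that list and of the p53 targets were 0.11 and 0.078. Without cKO 3 and cKO 5 the interferon list had a median of -0.45 (camera adjusted p = 0.0225, adjusted p = 0.655 with an estimated correlation). That list also passed preset camera without WT 3 alone (-0.32, 0.0150) and without cKO 3 alone (-0.32, 0.0232), and turned to 0.025 without WT 6 (0.555). The 4 Y chromosome genes were read in all 10 libraries and had a median of 0.33, with none past the test.

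Without cKO 3 and cKO 5, with fewer libraries in the test, the calls of 15 of the named genes ended while their signs stayed. The log2 fold changes were then larger for Nts (1.15), Bfsp1 (2.22), Rbp7 (2.14) and Srebf1 (-1.20), and smaller for Col3a1 (0.72), Slc51b (0.77), Chga (0.72), Col1a1 (0.88), Ccnd1 (1.04), Mast4 (1.01), Slc27a2 (-0.88), Cd36 (-1.01), Cyp2b10 (-1.16), Adh1 (-1.29) and Slc6a20a (-2.24). Among reported genes that kept their call, the change was larger for Acta1 (6.52), Mt1 (2.52), Ocm (1.90) and Tmigd1 (1.78). It was smaller for Slc34a2 (1.65), Dock11 (1.72), Lyve1 (1.47), Sult6b2 (-2.81) and Slc46a1 (-2.42). The same held for Cndp1 (-2.17), Cyp27a1 (-1.50), Tmprss15 (-2.13), Slc13a1 (-1.44) and Tsku (-1.30). Of the 25 alternatives, the call was lost in 14 for Slc51b, 13 for Nts, 12 for Cd36, 11 for Chga, 10 for Col1a1, 9 for Slc27a2 and Ccnd1, 8 for Cyp2b10 and 7 for Col3a1 and Srebf1. Altogether 11 of 36 lists passed camera with the preset correlation, 4 up and 7 down, and 0 with an estimated correlation. Of 100 splits drawn of the 10 libraries into groups of 5, the real one included, 49 put as many lists past the preset threshold, so the list calls did not exceed what other groupings of these libraries gave.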

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

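In each group of 5 libraries, a library was singled out when its gap to the nearest other library, divided by the range of the group, passed Dixon's 95% limit. Of 286 groups of values examined 19 passed, where chance alone gives about 14.3. No explanation is weighed for these values.

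Of the libraries labelled cKO, cKO 1 stood above the other 4 for Ocm (1078 against 565 to 600 normalised reads, gap ratio 0.907), Tmigd1 (4714 against 2165 to 2614, ratio 0.758), Rbp7 (413 against 118 to 159, ratio 0.766) and Guca2a, a goblet cell list gene (2604 against 1126 to 1269, ratio 0.857). It was also highest for the mean of the goblet cell list (ratio 0.772) and of the Y chromosome list (ratio 0.755). cKO 4 was highest for the acyl-CoA synthetase gene Acsl1 (646 against 292 to 342, ratio 0.799), and lowest for the B cell gene Cd79a (4.26 against 33.1 to 51.8, ratio 0.810) and for the means of the B and plasma cell list (ratio 0.757) and the T cell list (ratio 0.738). cKO 3 was lowest for the mean of the villus tip list (-1.20 against -0.55 to -0.29 on the log2 scale, ratio 0.713).

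Among the WT libraries, WT 5 was highest for Mmp7, a Paneth cell protease (456 against 137 to 192, ratio 0.717), for the mean of the B and plasma cell list (1.77 against -0.66 to -0.15, ratio 0.793) and for that of the MHC class II list (ratio 0.729). WT 1 was highest for Uty (406 against 247 to 277, ratio 0.766). WT 3 was highest for Agr2, a goblet cell gene (4199 against 2679 to 2977, ratio 0.765), and lowest for the mean of the neuron and glia list (ratio 0.753). WT 6 was highest for Col3a1 (1542 against 1081 to 1189, ratio 0.733) and lowest for the mean of the myeloid and mast cell list (ratio 0.780).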

How the results depend on the processing

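The comparisons with edgeR on recovered reads, without cKO 3 and cKO 5, with the clock covariate and over 8 libraries without the block were chosen after the data were seen; the others were planned. Of the called genes named by the fixed rule, Acta1, Dock11, Ocm, Lyve1, Tmigd1, Cndp1 and Tmprss15 passed in all 25 alternatives that refitted the genes. None of the called genes named by that rule changed sign. Of the genes it named that were not called in the main fit, 20 passed with DESeq2 and 13 without cKO 4. DESeq2 gave 316 higher and 411 lower genes against 62 and 124, and edgeR with library totals 83 and 73; the cause was not tested. A log2 fold change of at least 1 left 32 and 72, and an adjusted p under 0.01 left 10 and 14, by construction. Leaving out 1 library gave 12 (without WT 4) to 189 (without cKO 4) higher and 18 (without WT 4) to 422 (without cKO 4) lower genes. Fewer samples also entered without cKO 3 and cKO 5 (26 higher, 30 lower, 7 lists) and over the 8 libraries with shared replicate numbers (33 and 56). The clock covariate gave 26 and 22 genes and 6 lists, and a triglyceride list median of -0.24 no longer past the threshold (adjusted p = 0.0618; over all alternatives that leave out 1 library the median was -0.61 to -0.32). Camera with an estimated correlation passed 0 lists and fry 1 against 11. Deviations of libraries with the same replicate number correlated at 0.12, 0.02, -0.11 and 0.10. The best match carried the same number for 1 of the 4. With the number as a replicate block 49 higher and 85 lower genes and 15 lists passed, against 33, 56 and 12 on these 8 libraries without it. Whether the numbers pair the libraries was thus not settled. Some lists passed preset camera with the block but not in the main fit. These were fatty acid synthesis (median 0.50, camera adjusted p = 0.0491), xenobiotic metabolism (-0.45, 0.0178), B and plasma cells (-0.52, 0.0379) and neurons and glia (-0.36, 0.0373). Elavl1 turned to 0.033 with library totals and to 0.028 with totals without mitochondrial and top genes.

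The other values that changed sign belong to genes and lists not called in the report, and the cause was not tested. With library totals Cela1 turned to 0.10, and the medians of the cholesterol synthesis, p53 target and AU-rich element lists to 0.10, 0.078 and 0.11; with totals without mitochondrial and top genes the same 4 were 0.047, 0.076, 0.043 and 0.078. The AU-rich list turned to 0.00045 with the DESeq2-style factors in edgeR, 0.0047 with edgeR on recovered reads and 0.030 with voom, where p53 targets were at 0.0076. The adipocyte list turned to -0.074 with DESeq2, to -0.037 and -0.036 with these edgeR fits and to -0.74 with voom, as did Retn at -0.74. A minimum mean of 50 turned the enteroendocrine list to -0.017. Over the 8 libraries with shared numbers, with the replicate block and without it, cholesterol synthesis was 0.11, antimicrobial genes 0.020, T cells -0.086, myeloid cells -0.011 and duodenal genes -0.043. Without cKO 3 and cKO 5, and then with the clock covariate, p53 targets were 0.0030 and 0.012, the AU-rich list 0.014 and 0.017, T cells -0.22 and -0.23, myeloid cells -0.069 and -0.059, duodenal genes -0.15 and -0.15, ileal genes 0.27 and 0.29 and Lpin3 0.065 and 0.064; the unfolded protein list was -0.030 with the covariate. Leaving out 1 library at a time gave -0.21 to 0.068 for Cela1, -0.32 to 1.31 for Retn, -0.094 to 0.47 for mt-Nd1, -0.072 to 0.029 for the AU-rich list, -0.13 to 0.18 for T cells, -0.47 to 1.07 for adipocytes, -0.21 to 0.075 for cholesterol synthesis, -0.12 to 0.20 for duodenal and -0.36 to 0.012 for ileal genes, -0.017 to 0.37 for fatty acid synthesis, -0.41 to 0.028 for immediate early genes, -0.32 to 0.025 for the interferon response, -0.13 to 0.36 for mitochondrial genes, -0.024 to 0.22 for myeloid cells and -0.10 to 0.052 for p53 targets. At these depths and dispersions 8.84% of simulated 1.5-fold changes were recovered; depth alone was not varied.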

Other observations

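Beyond the lists, and chosen after their values were seen, these genes were called between the groups. They were not tested as sets, and their calls were not followed through the alternatives. Of all 186 calls, 44 remained without cKO 3 and cKO 5. Slc19a1, the reduced folate carrier, fell from 312 ± 52.5 to 111 ± 35.6 normalised reads (SD, n = 5 each, log2 fold change -1.53, limma adjusted p = 0.00518). The log2 fold change was -0.88 for the retinoic acid receptor gene Rara, -0.72 for the carotenoid oxygenase gene Bco2, -0.87 for Lipa, the acid lipase, -1.29 for Arsa, a sulfatase, and -1.24 for the transcription factor gene Tfeb. Sgk1, a kinase induced by steroid hormones, fell from 9179.5 ± 1921 to 3301 ± 1501 (SD, n = 5 each, log2 fold change -1.63). Srf, a transcription factor of actin genes, rose from 598 ± 146 to 1177 ± 169 (SD, n = 5 each, limma adjusted p = 0.0196). Cap1, which recycles actin monomers, fell from 9094 ± 659 to 4624 ± 597 (SD, n = 5 each, limma adjusted p = 0.00762). The cytoplasmic actin genes Actb and Actg1 were not called, at log2 fold changes of -0.43 and 0.66.

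The tests in the rest of this part were chosen after the results were seen, except those on swapped labels and on splits of the libraries. Of 126 possible splits of the 10 libraries 100 were drawn, the real one included. For genes called, 1 of the 100, the real one, reached 186 and the highest other drawn reached 12, which excludes chance at 0.05. For lists past camera, 49 of 100 splits reached 11 and the highest other reached 18. For the triglyceride list median 5 of 100 splits lay as far from 0 as -0.46, with the highest other at 0.55. Chance is thus not excluded for the lists past camera. For the triglyceride median, 5 of 100 is the 0.05 limit itself. The splits not drawn could move that share to either side, so chance is neither excluded nor shown there. The other splits with a triglyceride median that far from 0 (0.55, 0.53, 0.53 and 0.51) each differed from the real one only by cKO 4 changing places with 1 WT library. The triglyceride list mean of cKO 4, on the log2 scale relative to the WT mean, was 0.16, within the WT range of -0.12 to 0.18.

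Acta1 rose by 21088 normalised reads on average. Skeletal muscle in the samples is argued against, since the 5 measured muscle transcripts of a list of 15 had a median log2 fold change of -0.0040 (-0.36 to 0.16, with Ckm, muscle creatine kinase, at 160 and 157 normalised reads in WT and cKO), and 7 more stayed at or below 21.4 in every library. Reads moved from Acta2, Actg2, Actc1 and Actg1 are argued against as well, since their sum was higher by 22993 ± 10017 (SE). Actb was lower by 24458 ± 14477 (SE), and a shift of its reads stays open. A joint rise of serum response factor targets may be part of the pattern, since 28 measured targets without Acta1 had a median of 0.17 (camera p = 0.00424, and p = 0.218 with an estimated correlation), but Srf alone was called and the list was drawn up after Srf had been seen.

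Elavl1 did not differ between the groups past the test. A swap of single labels between the groups needs a library out of place in each group; over genes called without it, only 1 library of 10, cKO 4, lay nearer the other group's mean (distance 0.804 to WT and 0.843 to cKO), and no WT library did. Its Acta1 value of 22361 lay among those of the other libraries labelled cKO. Reads counted outside the deleted part of the gene cannot be told apart from an absent deletion, because the table has no values per exon; the interval allows a fall of at most 22.3%. Reads from cells other than the epithelium were not tested.

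The libraries cKO 3 and cKO 5 differed from the other 8 in clock genes. For 8 of 9 clock genes both lay beyond all others, Arntl upwards (374 and 600 against 64.9 to 186) and Per1, Per2, Per3, Dbp, Tef, Hlf and Ciart downwards; Npas2 overlapped. A candidate explanation is another time of day of collection, which cannot be told apart from an effect of genotype in some mice, because the labels give no times and the genes had been seen before. Without both libraries the list medians went from -0.46 to -0.24 for triglyceride synthesis, from -0.55 to -0.26 for the brush border and from 0.49 to 0.30 for proliferation. With 3 libraries left in cKO the spread of the list means (SE 0.20, 0.21 and 0.31) is, by a limit set after the values were seen, too wide to say whether these 2 libraries account for more than 50% of each shift.

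Sequence carried along with the targeted chromosome was tested as a hypothesis: within 20 Mb of Elavl1 on chromosome 8, 1 of 114 genes tested was called (Pnpla6, a phospholipase gene), against 185 of 13948 elsewhere (one-sided Fisher exact p = 0.782), which gives no sign of it. At the 1.33% called elsewhere, few calls arise among 114 genes, so the test could miss a small number of carried differences. Adipose transcripts varied without regard to genotype, with Adipoq at 0 in WT 1, WT 4, cKO 2 and cKO 5 and between 22.9 and 246 in the other 6 libraries.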
